A study of Mus musculus with 4 samples.

How the data were processed

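Contact maps of 4 in situ Hi-C libraries of mouse embryonic stem cells were used, 2 control libraries and 2 from cells in which MATR3 degradation was induced with 0.5 mM IAA. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The labels name no batch.

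The authors digested the chromatin with MboI, and the submitters' processing notes name HiC-Pro and mm10, with read filters and balancing settings not given in the sources used here. The deposited values are signal, ICE-balanced read pairs for each pair of 100-kb bins, with 1 map per library. The sum over pairs was equal for all bins of a library, and its total kept the number of read pairs. Bins are numbered through the genome. Chromosome borders were placed from mm10 lengths and checked against the values: each of the 19 junctions of autosomes and X was the lowest point of signal between neighbouring bins in all 4 libraries. Whole read pairs were recovered by dividing each value by 1 factor per bin, and 100% of the values were whole to within 0.01. The totals were 156544307 and 179641544 read pairs in control replicates 1 and 2 and 168904865 and 178068386 in degraded replicates 1 and 2. Of the non-zero pairs of bins, 72.7% and 73.5% held 1 read pair in the control and 72.5% and 72.4% in the degraded libraries, so results rest on sums over many pairs of bins. Recovered counts differed beyond sampling noise between every pair of libraries (chi-square test over 1-Mb blocks), so none was counted as a repeat of another. Spearman correlations of bin scores between libraries ranged from 0.986 to 0.996, across bins that are not independent replicates.

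Scores were computed for the 25151 bins of the 19 autosomes and X with signal in all 4 libraries, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The compartment score was the first principal component of the correlation matrix of observed over expected signal, per chromosome, scaled to SD 1 and oriented so that gene-rich bins are positive (A). The ratio of distal to local contacts was log2 of within-chromosome signal at over 3 Mb over that at 0.1 to 3 Mb. The inter-chromosomal share was log2 of between-chromosome over within-chromosome signal without the diagonal. The insulation score was log2 of the mean signal crossing a bin within 500 kb on each side, over the mean of the chromosome, and borders were its minima with a depth (prominence) of at least 0.2. Compartment strength was the mean of the A-A and B-B ratios over the A-B ratio, from the top and bottom 20% of bins at over 2 Mb. Blocks of 1 Mb were compared within chromosomes on log2 of scaled signal with a pseudocount of 1, centred per distance, for pairs with a mean of at least 20. Pairs of chromosomes were compared on log2 of observed over expected signal.

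Each bin or pair was tested with limma 3.58.1 in R 4.3.3 (linear model, moderated by empirical Bayes, with a mean-variance trend for the ratio of distal to local contacts, the inter-chromosomal share and 1-Mb pairs), all tests being two-sided. P-values were adjusted by Benjamini-Hochberg over all bins or pairs, and 0.05 was the threshold. Values with 1 number per library were compared by an exact two-sided permutation test, which cannot go below 0.333 with 2 against 2 libraries. The tests were tried on simulated data with 200 shifted bins per size, all sizes being planted in the same data. The compartment test called 7.5%, 88.5% and 100% of shifts of 0.2, 0.4 and 0.8, the distal-to-local test 2.5%, 75% and 100% of 0.1, 0.2 and 0.4, and the inter-chromosomal test 0%, 3% and 100% of 0.2, 0.5 and 1. The insulation test called 1.5%, 46% and 100% of shifts of 0.05, 0.1 and 0.2, and the test of 1-Mb pairs 14%, 57% and 91.5% of 0.3, 0.6 and 1.2. Planting many large shifts together eases the Benjamini-Hochberg threshold, so these shares are too high where few bins change. In the real libraries, compartment changes of 0.418 (bin of Mid1ip1) and -0.418 (bin of Fmr1) did not pass. A distal-to-local change of -0.221 (X, 53900001) did not pass either.

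Genes were placed in the bin of their midpoint on GRCm38 (mm10), because the gene table used here has no strand from which to take transcription starts. A bin is said to hold no protein-coding gene where no midpoint of such a gene lies in it. It can still lie within a long gene or hold a non-coding gene. The 14 lists (naive pluripotency, early differentiation, Hox, 2-cell, olfactory receptor, vomeronasal receptor, clustered protocadherin, histone, ribosomal protein, imprinted, long neuronal, chromatin architecture, fibroblast and hepatocyte genes) held 1842 genes, of which 1751 lay in measured bins. The last 2 mark other cell types. Lists were tested with camera at an inter-gene correlation of 0.01 on 3 scores, adjusted over the 42 tests. Named bins were the called bins with the largest change whose groups did not overlap, at most 10 per direction for the compartment score and 5 for the others, and otherwise the 3 per direction with the smallest p-values. The called pair of 1-Mb blocks, up to 4 called members of each list and 11 loci, among them Matr3, Gt(ROSA)26Sor and Sox2, were named too; a further locus chosen in advance is not reported here. Where no list member passed over all bins, those that passed over the list alone are given, a choice made after their values were seen, as was the naming of the pair called with precision weights. Apart from these later choices, the scores, tests, lists, loci and the rule for naming were chosen before the data were examined. The groups were compared by quintiles of compartment score and by the number of protein-coding genes in a bin. A comparison by GC content was not run, because no genome sequence was used here.

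Alternatives fixed before the data were examined were a block for the replicate number, robust moderation, each library left out in turn, other windows, distance limits and minimum signals, centring, quantile normalisation, bins with few contacts left out and maps thinned to equal depth. Added after seeing the data were precision weights for 1-Mb pairs, the compartment score without X, the centred share without the bins of fewest contacts, genes placed by their lower coordinate and gene lists with each library left out. Figures were drawn with matplotlib 3.10.9.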

Results

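In situ Hi-C, which counts how often pairs of DNA fragments are ligated in fixed nuclei, was done on E14TG2a mouse embryonic stem cells grown in 2i/LIF. The cells carried a degron tag (mAID) on both alleles of Matr3, which encodes a nuclear matrix protein. They also carried the plant F-box protein OsTIR1 at the ROSA26 locus, so that the auxin IAA triggers breakdown of the tagged protein. The 4 libraries fell into 2 groups, with 2 control libraries named for alcohol, the solvent of IAA, and 2 libraries from cells given 0.5 mM IAA, called degraded here. How long IAA was present was not stated in the labels, and no measurement of MATR3 protein was used here. The balanced maps held 156544307 and 179641544 read pairs in control replicates 1 and 2, and 168904865 and 178068386 in degraded replicates 1 and 2. The median bin of 100 kb held 11355.5 and 13225 read pairs in the control libraries and 12351 and 12909 in the degraded libraries. Positions are on mm10, values are mean ± SD with n = 2 per group, and changes are degraded minus control.

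The comparison of degraded with control libraries addresses whether loss of MATR3 alters the folding of chromosomes at scales of 100 kb and above. By the labels only the degraded libraries were given IAA, so a direct effect of IAA cannot be told apart from loss of MATR3. The division of the genome into the gene-rich A compartment and the gene-poor B compartment was similar in the degraded and the control libraries. All 20 bins of naive pluripotency genes lay in A in the control mean, as did all 20 bins of chromatin architecture genes, 9 of 9 Hox bins, 12 of 12 histone bins and 78 of 80 ribosomal protein bins. Of the 20 bins of long neuronal genes 0 lay in A, while 63 of 344 olfactory receptor bins, 9 of 162 vomeronasal receptor bins and 1 of 17 bins of 2-cell genes did. Early differentiation genes had 12 of 16 bins in A, imprinted genes 11 of 17, clustered protocadherins 6 of 8, fibroblast genes 5 of 10 and hepatocyte genes 5 of 9. Of 25151 bins, 10772 (42.8%) were A in all 4 libraries and 13391 (53.2%) were B in all 4.

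No bin passed the limma test of the compartment score (0 of 25151, with 1680 bins at an unadjusted p under 0.05 and a smallest adjusted p of 0.535). Those 1680 are 6.68% of bins, against 4.14% and 4.15% for the other 2 ways of pairing the libraries. The 3 ways use the same 4 libraries and are not independent: a difference along 1 way widens the spread in the others. Any of the 3 could also rank first by chance. The bins with the smallest p-values all lay on X and did not pass. The bin of Mid1ip1 (X, 10700001 to 10800000) had a score of 0.181 ± 0.0635 in control and 0.599 ± 0.0532 in degraded libraries, and the bins at 20200001 and 50700001, which hold no protein-coding gene, were also higher. The bin of Fmr1, the gene silenced in fragile X syndrome (X, 68600001 to 68700000) had 0.837 ± 0.0875 and 0.419 ± 0.0572. The bin of 4930519F16Rik at 103200001 and a bin without a protein-coding gene at 120800001 were also lower. X held 51 of the 100 bins with the smallest p-values, against 63 and 66 for the other 2 ways of pairing the libraries. The sign of the score differed between the groups in 108 bins (0.429%), of which 76 were B in control and A in degraded libraries and 32 the reverse. The other 2 ways of pairing the 4 libraries gave 94 such bins (50 and 44 by direction) and 77 (38 and 39). The 108 bins had a median absolute score of 0.0178, and with scores beyond 0.2 on either side 0 bins switched. Leaving out control replicate 1 gave 13 called bins and leaving out control replicate 2 gave 16, with the remaining control library assumed to vary like the degraded libraries. The median 95% interval of a bin's change reached 0.133 score units to either side.

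Contacts between and within compartments also had nearly the same strength. Compartment strength was 3.46 ± 0.134 in control and 3.46 ± 0.00123 in degraded libraries (exact permutation test, two-sided, p = 1). Control replicate 1 stood at 3.55 and control replicate 2 at 3.36, on either side of both degraded libraries. The difference was 0.1002 without control replicate 1 and -0.0898 without control replicate 2. Contacts among the B bins with the lowest scores had an observed/expected ratio of 1.3733 ± 0.00674 in control and 1.3675 ± 0.000127 in degraded libraries. These ratios did not overlap (exact p = 0.333, the smallest that 2 against 2 libraries allow), but did with the top and bottom 10% of bins in place of 20% (exact p = 1). Their difference was -0.0059 with all libraries, -0.0011 without control replicate 1 and -0.0106 without control replicate 2. The ratio among A bins was 1.72 in both groups and that between A and B bins 0.448 in control and 0.446 in degraded libraries (exact p = 1 for both).

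Within chromosomes, contacts at 1 to 30 Mb made up a slightly smaller share of the signal in both degraded libraries than in both control libraries. The share at over 1 to 3 Mb was 13.1379% ± 0.0410 in control and 13.0657% ± 0.00346 in degraded libraries. The share at over 3 to 10 Mb was 10.8% ± 0.0907 and 10.6% ± 0.0185, and that at over 10 to 30 Mb was 13.5% ± 0.237 and 13.2% ± 0.0276. Each of these 3 bands gave an exact two-sided p of 0.333, the smallest possible, and 1 of the 3 ways of pairing 4 libraries gives such a separation by chance. The difference at 10 to 30 Mb was -0.209 percentage points with all libraries, -0.377 without control replicate 1 and -0.0413 without control replicate 2. Without that library the difference was -0.0432 at 1 to 3 Mb, against -0.0722 with all, and -0.123 at 3 to 10 Mb, against -0.187. At 10 to 30 Mb the groups overlapped when contacts within a bin were counted. Contacts at 0.1 to 1 Mb (49.3% ± 0.852 and 49.8% ± 0.0588) and at over 30 Mb (13.3% ± 0.483 and 13.2% ± 0.00912) overlapped between the groups (exact p = 1 for both). Their differences changed sign without control replicate 2, to -0.0922 and 0.29995 percentage points.

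**Figure D1:**
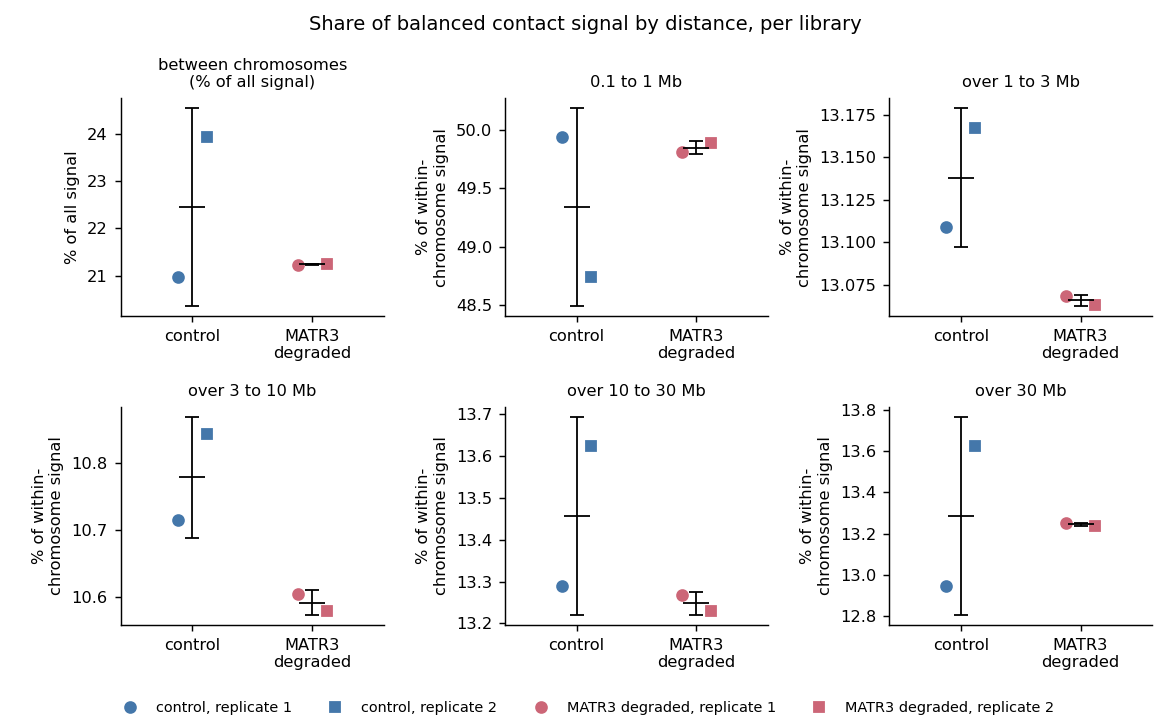
Percent of balanced signal between chromosomes and percent of within-chromosome signal in bands of distance, contacts within a bin left out, with a point for each of the 4 libraries and the mean ± SD of each group. The degraded libraries lie at 21.2% between chromosomes, while control replicate 2 lies apart at 23.9%.

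Per bin, the balance of contacts beyond 3 Mb to those nearer than 3 Mb passed the limma test at no locus (0 of 25151 bins, 807 at an unadjusted p under 0.05, smallest adjusted p 0.252). Without control replicate 1 the test called 3443 bins, 3438 of them lower in the degraded libraries, and without control replicate 2 it called 63, of which 40 were higher, the lone control being assumed to vary like the degraded libraries. The median change over bins was -0.026 with all libraries and 0.0092 without control replicate 2 (log2). The bins with the smallest p-values did not pass. Lower values were seen in a bin of chromosome 12 with Gm2042 and Gm2046 (87900001 to 88000000, -0.50 ± 0.071 in control and -0.72 ± 0.042 in degraded libraries). They were also seen in bins without a protein-coding gene at 53900001 on X and 30300001 on 8. These bins held few reads, at percentiles 0.0557, 2.63 and 3.28 of all bins. Higher values were seen at Phka2 on X (160500001 to 160600000, -1.12 ± 0.081 and -0.95 ± 0.060) and in bins without a protein-coding gene at 52700001 on 14 and 17300001 on X. Their read pairs lay at percentiles 12.3, 4.82 and 13.4 of all bins. The median 95% interval of a bin's change reached 0.10 log2 units to either side.

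Relative to each library's median, the ratio of distal to local contacts was lower in both degraded libraries in the bins with the lowest compartment scores. In the quintile of bins with the lowest compartment scores the median was -0.00100 and 0.00525 in control and -0.0122 and -0.0164 in degraded libraries (log2). The next quintile was also lower, at -0.0447 in the control mean and -0.0526 in the degraded mean. The middle, the fourth and the highest quintile were higher, at 0.00994 and 0.0151, 0.0694 and 0.0790, and -0.0250 and -0.0176, and centring on the median raises some quintiles where others are lower. Without centring, the lowest quintile stood at -0.78 and -0.70 in control replicates 1 and 2 and at -0.78 and -0.79 in the degraded libraries, control replicate 1 lying 0.00072 above the higher degraded library. The lowest quintile was lower in the degraded mean on 18 of 20 chromosomes, which are not independent replicates.

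**Figure D2:**
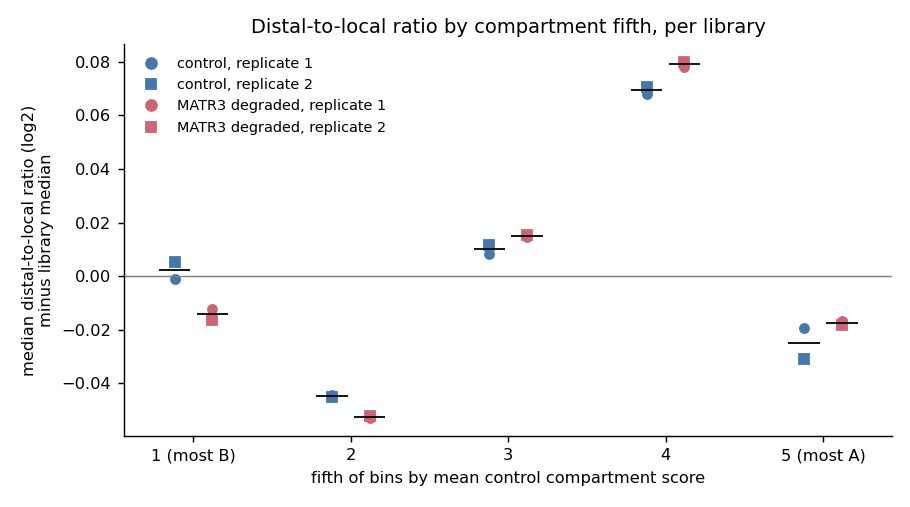
Median ratio of distal to local contacts relative to the library median (log2) for the quintiles of bins ordered by control compartment score, with a point for each of the 4 libraries and a bar for each group mean. In the lowest quintile the degraded libraries lie at -0.0122 and -0.0164 and the control libraries at -0.00100 and 0.00525.

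Contacts between chromosomes differed more between the control libraries than between the groups. With contacts within a bin left out, they made up 20.97% and 23.93% of balanced signal in control replicates 1 and 2, and 21.2% ± 0.0107 in degraded libraries (exact p = 1). With those contacts counted, the shares were 18.12% and 21.01%, and 18.4% ± 0.0231. The group difference was -1.21 percentage points with all libraries and 0.273 without control replicate 2. No bin passed the limma test of the inter-chromosomal share (0 of 25151, 15 at an unadjusted p under 0.05, smallest adjusted p 0.854). The median 95% interval of a bin's change reached 0.336 log2 units to either side, while the changes had an SD of 0.0497 across bins. The difference between the control libraries enters the spread of every bin, so this test could find only large changes. The lowest p-values belonged to bins without a protein-coding gene and with lower values. They lay on 14 at 109900001, on X at 24600001 and on 1 at 116800001 (-1.84 ± 0.073 in control and -2.42 ± 0.0078 in degraded libraries). Their read pairs were at percentiles 0.398, 0.227 and 21.0 of all bins. Among bins with higher values the lowest p-value belonged to a bin without a protein-coding gene on 17 at 39800001. That bin held a mean of 40057 read pairs, at percentile 99.996. Next, with overlapping groups, were the bin of Lars2 on 9 (123400001 to 123500000) and a bin without a protein-coding gene on 11 at 118800001. Without control replicate 1 the test called 25099 bins, all lower, and without control replicate 2 it called 424, of which 313 were higher, with the lone control assumed to vary like the degraded libraries. After each library was centred on its median, 65 bins were called, 64 of them lower in the degraded libraries. Their number and direction depended on which libraries were used, as given under the other observations.

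Of the 190 pairs of chromosomes, none passed the limma test of observed over expected contact (0, with 6 at an unadjusted p under 0.05 and a smallest adjusted p of 0.585). Without control replicate 1, 9 pairs were called, the lone control library being assumed to vary like the degraded libraries. The median 95% interval of a pair's change reached 0.0097 log2 units to either side.

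Insulation, which is low at domain borders, changed in 2 of 24745 bins, and in 5 (2 higher and 3 lower) with the replicate number as a block. The bin of Eif3j1 and Spg11 on chromosome 2 (122000001 to 122100000) was a border in both control libraries. Its score rose from -0.76 ± 0.034 to -0.57 ± 0.011, a weaker insulation (change 0.19, SE 0.022, adjusted p = 0.0307). In degraded replicate 1 this bin, at -0.58, was no longer a border, and a lower minimum of -0.61 lay 300 kb away at 122300001. The bin of Rhox2b, Rhox4b and Rhox2c, which holds 6 genes of the Rhox cluster of homeobox genes on X (37400001 to 37500000), fell from 0.037 ± 0.011 to -0.20 ± 0.010 (change -0.24, SE 0.020, adjusted p = 0.00155). This bin held a mean of 2556 read pairs, at the 0.207th percentile of all bins, and its genes are close paralogues. An unadjusted p under 0.05 was reached by 2101 bins (8.49%), against 3.84% and 3.50% for the other 2 ways of pairing the libraries, which called 1 and 0 bins. As for the compartment score, these ways are not independent, and any of them could rank first by chance. No bin was called without degraded replicate 1 (Eif3j1 and Spg11 adjusted p = 0.737, Rhox bin 0.106) or without degraded replicate 2 (0.495 and 0.0883), with 1436 and 1486 bins at an unadjusted p under 0.05. The changes then were 0.19 and 0.18 for Eif3j1 and Spg11 and -0.25 and -0.23 for the Rhox bin, about as large as with all libraries. Without control replicate 1 and control replicate 2, 82 and 123 bins were called. In each of these fits the lone library was assumed to vary like the other group. With a window of 300 kb no bin was called (1666 at an unadjusted p under 0.05 and an adjusted p of 0.675 with a change of 0.16 for Eif3j1 and Spg11), and with 1 Mb the Rhox bin was not called (0.113, change -0.093).

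**Figure D3:**
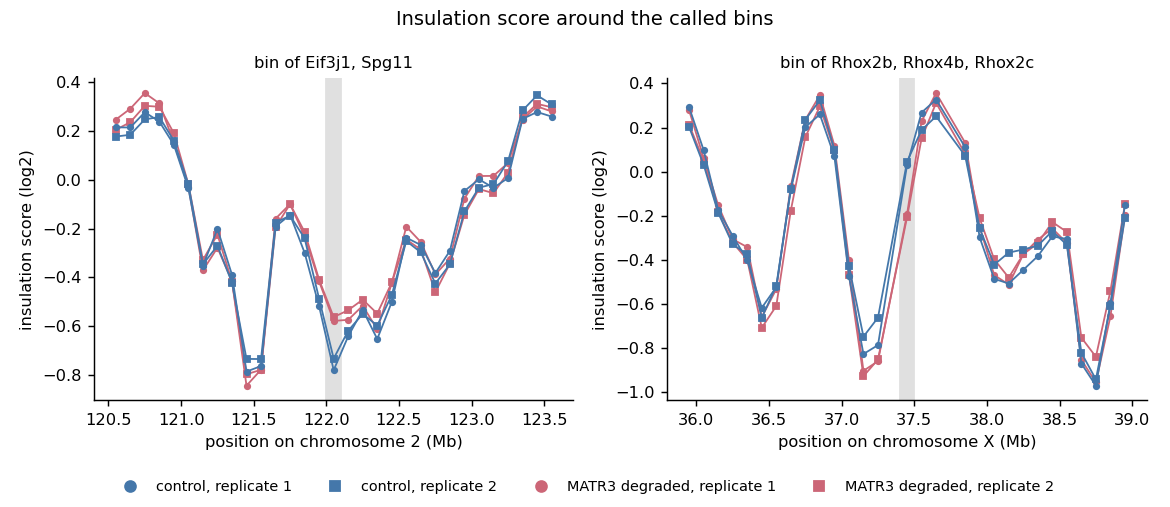
Insulation score (log2) against position (Mb) around Eif3j1 and Spg11 on chromosome 2 and around Rhox2b on X, with a line for each of the 4 libraries. In the shaded called bin the degraded libraries lie at -0.58 and -0.56 for Eif3j1 and at -0.19 and -0.21 for Rhox2b.

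The number and depth of domain borders overlapped between the groups with the window of 500 kb. Control libraries had 2405 ± 25.5 borders and degraded libraries 2412.5 ± 4.95 (exact p = 1), with mean depths of 0.83 ± 0.0053 and 0.83 ± 0.0014 log2 units (exact p = 0.667). The difference of 7.5 borders was 25.5 without control replicate 1, -10.5 without control replicate 2 and -9.5 with a window of 300 kb. That in depth was 0.0047 with all libraries, 0.0084 without control replicate 1 and 0.00093 without control replicate 2. With a window of 300 kb the depths did not overlap, at 0.85 ± 0.0076 and 0.86 ± 0.00055 (exact p = 0.333, the smallest possible). Between libraries of different groups 94.9% to 96.2% of borders were shared within 1 bin, and between libraries of the same group 94.4% to 96.0%.

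Among 170480 pairs of 1-Mb blocks within chromosomes, the limma test called 1 pair. Contact between 4000001 to 5000000 and 51000001 to 52000000 on chromosome 14, 47 Mb apart, fell by 1.19 on the log2 scale (SE 0.14, adjusted p = 0.0404). It rested on 17 and 23 read pairs in control and 11 and 12 in degraded libraries, and its adjusted p was 0.627, with a change again of -1.19, when pairs were weighted by the precision their read pairs give. That weighting called instead the pair at 41000001 and 93000001 on chromosome 1 (88 and 116 read pairs in control, 170 and 148 in degraded libraries, change 0.73, adjusted p = 0.0230). The other 2 ways of pairing the libraries called 0 and 3 pairs, and 9476 pairs had an unadjusted p under 0.05. With the replicate number as a block 46 pairs were called, 24 higher and 22 lower. Leaving out degraded replicate 1 or 2 gave 105 and 124 called pairs, and leaving out control replicate 1 or 2 gave 86 and 164, the lone library being assumed to vary like the other group.

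Of 14 gene lists tested with camera in 3 scores, 1 result passed over the 42 tests. Insulation of olfactory receptor bins rose from 0.0068 ± 0.0011 to 0.016 ± 0.00097 (343 bins, mean change 0.0096, adjusted p = 0.0386, and adjusted p = 0.848 with an estimated correlation). The estimated correlation was -0.0007, below the 0.01 set, so correlation between bins did not raise the adjusted p. That setting rests on the few residual degrees of freedom that 4 libraries leave, so hardly any list could pass under it. The result was not past the threshold without degraded replicate 1 (0.0810), degraded replicate 2 (0.113), control replicate 1 (0.115) or control replicate 2 (0.211), the lone library being assumed to vary like the other group. No olfactory receptor bin was called by limma alone (0, with 50 at an unadjusted p under 0.05). For the other lists the adjusted p was 0.638 or more in the compartment score, 0.257 or more in the ratio of distal to local contacts and 0.140 or more in insulation. Naive pluripotency bins had a mean compartment score of 1.30 ± 0.0264 in control and 1.30 ± 0.0119 in degraded libraries, and Hox bins 1.26 ± 0.0192 and 1.28 ± 0.00177. Chromatin architecture bins had 1.45 ± 0.00501 and 1.45 ± 0.0419, histone bins 1.28 ± 0.0261 and 1.27 ± 0.00360, and ribosomal protein bins 1.38 ± 0.00738 and 1.39 ± 0.000625. Early differentiation bins had 0.857 and 0.853, clustered protocadherins 0.541 and 0.542, fibroblast genes 0.404 and 0.402, hepatocyte genes 0.377 and 0.371, and imprinted genes 0.249 and 0.234. Scores were -0.988 and -1.01 for long neuronal genes, -0.684 and -0.693 for olfactory receptors, -0.742 and -0.744 for vomeronasal receptors and -0.581 and -0.576 for 2-cell genes.

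The smallest p-values among the other lists belonged to insulation of early differentiation bins, at -0.019 in control and -0.041 in degraded libraries (adjusted p = 0.140), and to the ratio of distal to local contacts of vomeronasal receptors, at -0.82 and -0.86 (adjusted p = 0.257). Adjusted over the list alone, the bins of Zscan4b and Zscan4d, zinc finger genes of the 2-cell stage, on chromosome 7 (10900001 to 11000000 and 11100001 to 11200000) passed for the ratio of distal to local contacts, which fell by 0.16 in each (adjusted p = 0.0252, and 0 bins over all bins tested). The bin between them, that of Zscan4c, had a change of -0.0013, with overlapping groups. Both calls were lost without degraded replicate 1 (adjusted p = 0.246, changes of -0.21 and -0.20), without degraded replicate 2 (0.979, -0.11 and -0.13) and with a replicate block (0.0598, with the changes as with all libraries and no block). The bin of Zscan4b held a mean of 3041.5 read pairs, at the 0.421th percentile. The bin of the histone genes H2bc6, H1f4 and H2ac6 on chromosome 13 (23600001 to 23700000) passed for insulation, which fell by 0.084 adjusted over the list alone (adjusted p = 0.0283, and 0 histone bins over all bins tested). This call was lost without degraded replicate 1 (0.213, change -0.082), degraded replicate 2 (0.0859, -0.086) and control replicate 2 (0.303, -0.062). Camera sets each list against all other bins, so its direction and the list's own change differed in some lists. In the ratio of distal to local contacts, protocadherins, early differentiation, fibroblast and imprinted genes had a negative mean and median and a test pointing up. In the compartment score, fibroblast genes had a negative mean and median and a test pointing up, naive pluripotency genes a negative mean and test and a positive median, and 2-cell genes a positive mean and test and a negative median. In insulation, naive pluripotency genes had a negative mean and test and a positive median.

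At 11 loci chosen in advance no score changed past the threshold (limma, 0 of 11 in each of 4 scores, with 2 insulation bins at an unadjusted p under 0.05). The tagged gene itself, Matr3 (18, 35562158 to 35592045), had a compartment score of 1.78 ± 0.0583 in control and 1.77 ± 0.0204 in degraded libraries. Among the core pluripotency factors, Sox2 had 1.70 ± 0.0941 and 1.80 ± 0.140, Nanog 1.201 ± 0.101 and 1.21 ± 0.0318, and Pou5f1 1.59 ± 0.00888 and 1.602 ± 0.0313. Esrrb had 1.77 ± 0.0547 and 1.80 ± 0.0789, Klf4 0.746 ± 0.0843 and 0.790 ± 0.103, and Zfp42 0.154 ± 0.0256 and 0.109 ± 0.00512. Hoxd13 had 0.883 ± 0.0808 and 0.912 ± 0.0443, and H19 0.341 ± 0.0622 and 0.258 ± 0.00140. Zscan4c lay in B, with -0.663 ± 0.00288 and -0.684 ± 0.0579, and Gt(ROSA)26Sor, the site of OsTIR1, in A, with 1.50 ± 0.112 and 1.48 ± 0.00895. Insulation at Gt(ROSA)26Sor was -0.74 ± 0.027 and -0.81 ± 0.0025 (adjusted p = 0.539) and at Zfp42 -0.23 ± 0.0036 and -0.29 ± 0.010 (adjusted p = 0.539).

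**Figure D4:**
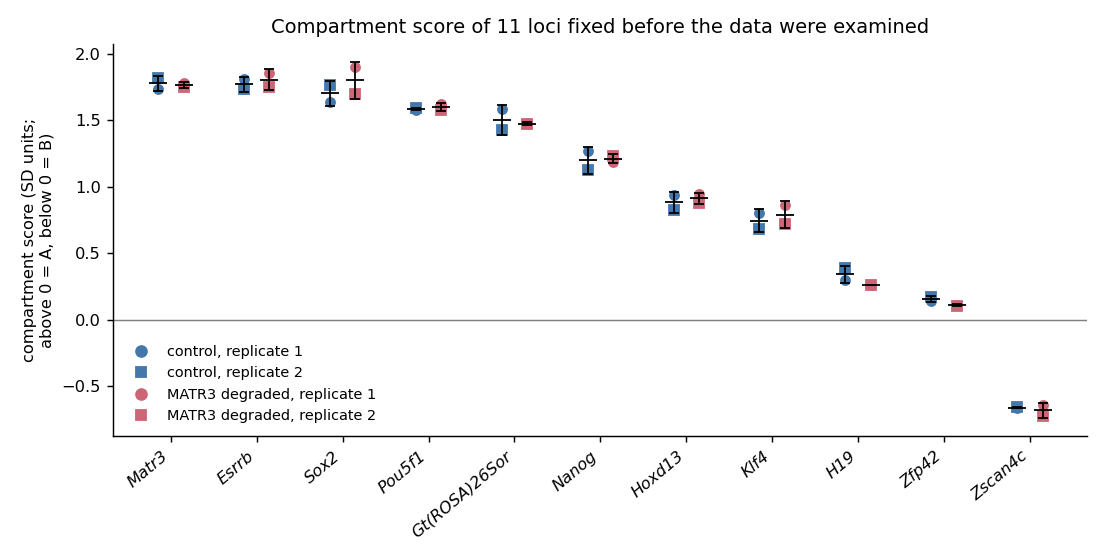
Compartment score (SD units of the chromosome) at the 11 loci chosen in advance, with a point for each of the 4 libraries and the mean ± SD of each group. The bin of Zscan4c lies below 0 in all 4 libraries, near -0.663, and the other 10 lie above 0.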

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

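Precision weights for 1-Mb pairs, the compartment score without X, the centred inter-chromosomal share without bins of few contacts, genes placed by their lower coordinate and gene lists with each library left out were alternatives chosen after seeing the data. Of 141 values of 20 results under alternatives, 106 stayed within their limit, which is 1.5 times for a count and 1 SD between replicates for a difference in values, and 35 moved beyond it. With 2 libraries per group, leaving 1 out cannot move a difference in values beyond 1 such SD, apart from rounding. Those entries were therefore fixed in advance and do not speak for the stability of the differences. Staying within it does not mean the same direction: 10 of the 106 have the other sign, among them between-chromosome contacts (0.273 percentage points) and compartment strength (-0.0898) without control replicate 2.

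Leaving out each library in turn gave 0 to 16 called bins for the compartment score, 0 to 3443 for the ratio of distal to local contacts, 0 to 25099 for the inter-chromosomal share and 0 to 123 for insulation. It gave 86 to 164 called 1-Mb pairs, 0 to 9 chromosome pairs and 281 to 292 bins with a switched sign. The difference in compartment strength then ranged from -0.0898 to 0.1002, that in B-B contacts from -0.0106 to -0.0011, and 0 gene lists passed in each of the 4 fits. Control replicate 2 has the highest share of between-chromosome contacts, and leaving out a control leaves the spread to the degraded libraries, which differ less in that share. Each lone library was assumed to vary like the other group. The count of bins with a switched sign, 108 with all libraries, can only rise when a library is left out. Fewer libraries must then share the sign. The moves of this count were therefore fixed in direction and do not speak for dependence on single libraries.

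Centring each library on its median raised the bins called for the inter-chromosomal share to 65, and to 43 without the 10% of bins with the fewest contacts. Insulation gave 5 bins with a replicate block, 0 with a window of 300 kb, in which the Rhox bin has no value, and 1 with a window of 1 Mb. The 1-Mb pairs gave 46 with a replicate block. With a score beyond 0.2 on either side, 0 bins switched sign. The difference in contacts at 1 to 3 Mb was -0.1075 percentage points with contacts within a bin counted, and that in border depth was 0.0098 with a window of 300 kb, where the groups no longer overlapped. With an estimated correlation 0 gene lists passed, but hardly any could under that setting, which rests on few residual degrees of freedom. Where nothing else is said, the cause was not tested. The deviations of libraries of the same number from their group means were correlated across bins at -0.00219, 0.00628, 0.0229 and 0.0264 in the 4 bin scores, -0.0081 across 1-Mb pairs and 0.121 across the 190 chromosome pairs, whose members are not independent.

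The bin of Rhox2b and the called pair on chromosome 14 rested on few reads. The pair had an adjusted p of 0.627 with precision weights, against 4.0e-05 to 0.0480 under the other alternatives, and its change with the weights was again -1.19.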

Other observations

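The tests of the bins' read depth, of a regional change and of between-chromosome background in control replicate 2 were chosen after the results they test were seen.

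Bins with more protein-coding genes had higher compartment scores in both groups, a direction set by the way the score was oriented. Bins without such genes had a median compartment score of -0.709 ± 0.00479 in control and -0.715 ± 0.00145 in degraded libraries, and bins with 5 or more had 1.44 ± 0.00703 and 1.46 ± 0.00316. Insulation was 0.095 ± 0.0019 and 0.095 ± 0.00091 in bins without such genes and -0.26 ± 0.0051 and -0.26 ± 0.0015 in bins with 2.

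After each library was centred on its median, 64 bins had a lower inter-chromosomal share in the degraded libraries (median change -0.20), of which 51 (79.7%) held no protein-coding gene, against 56.2% of all bins. Leaving out degraded replicates 1 and 2 gave 19 and 23 called bins, leaving out control replicate 1 gave 21 (10 higher and 11 lower) and control replicate 2 gave 68 (63 lower), of which 9 and 38 were among the 65 called with all libraries, and the other 2 ways of pairing the libraries gave 0 and 3. Low read depth of the bins stays open: without the 10% of bins with the fewest contacts 34 of the 36 lower bins still tested were called, but 28 of the 64 (43.75%) were among those 10%. Reads of another origin in the controls are argued against only where their partners would be spread like all reads. Of the partners of the extra contacts, 24.4% (bootstrap SD 1.33) lay in the quintile of bins with the lowest compartment scores. This was closer to the 19.6% of adjacent bins that were not called than to the 15.6% of all reads, but above both. Reads of another origin whose partners favour that quintile therefore stay open. A regional change after MATR3 degradation stays open and cannot be told apart from a change at single bins. The adjacent bins that were not called themselves changed by 23.7% of the called bins' change (bootstrap SD 3.09), too close to the limit of 25% set for this test. Called neighbours were left out, which tends to lower that share.

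The ratio of distal to local contacts, relative to the library median, was lower in the degraded libraries in the quintile of bins with the lowest compartment scores. Thinning all libraries to the same depth left a difference of -0.0156, but cannot decide on read depth. Thinning lowers distal and local contacts alike, so on average their ratio is nearly kept whatever its cause. Depth did not separate the groups: control replicates 1 and 2 held the fewest and the most read pairs (156544307 and 179641544). The use of control scores to define the quintiles is argued against by a difference of -0.0164 with quintiles taken from the degraded libraries. More between-chromosome background in control replicate 2 stays open: control replicate 1, a lone library, lay 0.0112 above the higher degraded library (log2) relative to the median, where the degraded libraries differed by 0.00422, but 0.00072 above it without centring, where they differed by 0.0093. An effect of MATR3 loss, a direct effect of IAA and unlabelled differences between cultures or library preparations also stay open, as untested.

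Bins of X led the list of compartment scores with the smallest p-values, with 51 of the first 100, although X holds 5.90% of bins. The other 2 ways of pairing the libraries gave 63 and 66, so the lead of X did not depend on the groups. The median bin of X held 0.479 (control) and 0.471 (degraded) of the read pairs of the median autosomal bin, and the SD within groups was 0.134 on X and 0.0652 on autosomes. This is consistent with the lower read depth of X as the source of its lead, with no biological explanation tested.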
